A study of Mus musculus with 7 samples.

How the data were processed

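Ribosome-bound RNA was collected from retinas of adult mice of the RiboTag kind, in which a tamoxifen-inducible Cre under the Cdh5 promoter puts an HA tag on the ribosomal protein Rpl22 in endothelial cells. Tagged ribosomes were pulled down with an anti-HA antibody, and QuantSeq libraries, which read the 3′ ends of polyadenylated transcripts, were made from the bound RNA, per the labels' protocols. Mice had received a control IgG (3 libraries) or an antibody against Dll4, a ligand of Notch receptors (4 libraries). The labels do not say that each library is a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

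Per the submitters' processing notes, the tools were cutadapt, TopHat2 and bedtools, named without versions or roles. The same notes name hg19, a human genome build, although the gene symbols in the deposited table are mouse symbols, of which 10786 of the 10899 tested (98.96%) matched GENCODE M21. No coordinate is given here for that reason. The annotation, the counting rule and whether strand was used are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain. In the table, 179 genes with at least 100 reads, in 67 sets, had the same reads as another gene in every library, Hba-a1 and Hba-a2 among them.

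The deposited table holds log10 values for 12756 genes in 7 libraries. Turned back from the log10 scale, the deposited values were CPM (reads scaled to a fixed library total) plus 1, and the CPM summed to 1000000 in each library. Within a library 100% of the CPM values were whole multiples of the CPM of a single read (tolerance 1e-06), so that whole reads could be computed. The listed genes held 1356192 to 1771086 reads per library, which is 6.78% to 8.86% of the 20000000 reads that the labels give as the median. Each listed gene had at least 10 reads over the 7 libraries. A floor of 3 reads corresponds to 1.69 to 2.21 CPM. The protocol names no molecular identifiers, so reads are not independent molecules.

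Libraries are named by the number in the table's column. Anti-Dll4 1 to 4 and control IgG 3 and 4 match sample titles. The column called here control IgG 1 matches no control title by number, and the remaining control title carries the number 15. That column was used as a control library with no number of its own.

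Values were converted to log2(CPM + 1). Genes with at least 1 CPM in at least 3 libraries were tested, 10899 in all, with limma 3.58.1 in R 4.3.3 (linear model with the antibody as the only term, empirical Bayes with a mean-variance trend, two-sided). Genes at a Benjamini-Hochberg adjusted p under 0.05 are called past the threshold. Fold changes are differences of mean log2(CPM + 1), and errors of a change are limma standard errors. The added 1 shrinks the changes of low genes. A single library with few or no reads can instead make a change larger than that of the mean CPM. Cd34, for example, changed 10.3-fold on this scale, with mean CPM of 96.4 in control and 329 in anti-Dll4 libraries. The design had assumed log2 values, and the conversion from log10 kept its test as fixed.

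Before the data were examined, 39 gene lists were fixed, covering endothelial identity, pathways and markers of other retinal cell types. The 37 lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, beside camera with an estimated correlation, fry, and an exact permutation test of the library means of each list over the 35 splits of 7 libraries into 3 and 4, whose smallest two-sided p is 0.0286. The named genes are Dll4, 6 Notch genes that were tested (Hey1, Hes1, Nrarp, Notch1, Notch4 and Jag1), and Hey2, Efnb2, Gja4 and Gja5, whatever their result. Also named are up to 10 genes per direction with the largest changes among those past the threshold with a mean log2 value of at least 3 and groups that do not overlap, and from each list up to 4 members past the threshold or, failing that, up to 2 with the smallest p. Other genes in the text, among them those named because they passed only when adjusted over their own list, were chosen after their values were seen. A gene that the rule takes is not reported here.

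Data were simulated with each gene's spread averaged over the 2 groups, with 11655 genes tested and 200 genes changed. The gene test recovered 4.48% of genes changed 2-fold, 14.9% of those changed 4-fold and 28.8% of those changed 8-fold, with 2 false calls among 34. The real spread was unequal (median SD 1.05 in control and 1.56 in anti-Dll4 libraries), so these false calls do not test the error rate there. The changed genes were drawn only from genes above a minimum mean CPM, so recovery over all tested genes may be lower. The list test made 0 calls among 37 simulated lists without a change and called a list shifted by 1.5 log2. The simulated genes were drawn independently of each other. Those 0 calls therefore do not test how often lists whose members vary together are called falsely. Alternatives covered the filter, normalization, pseudocount, variance model, library weights, a rod marker covariate, replicate blocks, each library left out, other list tests and other thresholds. Limma's voom on the whole reads, a pseudocount of 0.25, scaling on endothelial markers and a block on column numbers were added after the data were seen. Transcript lengths came from GENCODE M21. Figures were drawn with matplotlib 3.10.9.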

Results

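The data describe RNA pulled down with tagged ribosomes from adult mouse retinas. Treatment with an antibody against Dll4 was compared with a control IgG. Dll4 is a Notch ligand made by arterial endothelial cells and by the tip cells of growing vessels. RNA was pulled down with tagged endothelial ribosomes in 3 control IgG and 4 anti-Dll4 libraries, and it held much RNA of other cells: rod markers made up 2.83% of the control CPM and general endothelial markers 0.227%. No library of RNA before the pull-down is among the samples, so enrichment of endothelial RNA was not measured. A change can therefore not be assigned to endothelial cells with certainty. The table held 1356192 to 1771086 reads per library over 12756 genes. Correlations across genes, which are not independent replicates, were 0.61 to 0.65 between control libraries, 0.55 to 0.60 between anti-Dll4 libraries and 0.52 to 0.63 between the groups. The median SD of a tested gene on the log2(CPM + 1) scale was 1.05 between control libraries and 1.56 between anti-Dll4 libraries.

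The comparison of anti-Dll4 with control IgG asked which transcripts of the pulled-down RNA differ when Dll4 is blocked. Of 10899 genes tested, 13 passed the threshold, and all 13 were higher in the anti-Dll4 libraries. Mgp, a secreted inhibitor of calcification and of BMP signalling, rose from 183 ± 41.4 CPM (SD, n = 3) to 1308 ± 392 CPM (SD, n = 4), a log2 change of 2.81 ± 0.35 (SE). Ly6a, which encodes the surface antigen Sca-1, rose from 98.0 ± 19.4 to 699.7 ± 115 CPM, a log2 change of 2.83 ± 0.40. Ctla2a, an inhibitor of cathepsin L-like proteases, rose by 2.76 ± 0.44 and Sparc, a matricellular protein of basement membranes, by 2.74 ± 0.47. Igfbp7, a secreted protein that binds insulin-like growth factors, rose by 2.41 ± 0.42, and Ly6c1, a surface antigen of mouse endothelium, by 2.06 ± 0.38.

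Tmsb4x, which encodes the actin-sequestering peptide thymosin beta 4, rose by 1.72 ± 0.22 on the log2 scale, from 1465 ± 396 CPM to 4784 ± 910.1 CPM. Arpc3 and Arpc1b, subunits of the Arp2/3 complex that nucleates branched actin, rose by 2.02 ± 0.38 and 1.79 ± 0.34. Ddit4, an inhibitor of mTORC1 signalling induced by hypoxia and other stresses, rose by 1.64 ± 0.28. The remaining members were Rps9, a protein of the small ribosomal subunit (1.52 ± 0.29), Rpl13a of the large subunit (1.33 ± 0.26) and Tpt1 (1.29 ± 0.26). Adjusted p ran from 0.000677 for Mgp to 0.0465 for Tpt1 and Rpl13a (limma). For each of the 13, the 4 anti-Dll4 libraries lay above the 3 control libraries. Ly6a and Ly6c1 belong to a family of similar genes, and ribosomal protein genes, Tpt1 and Tmsb4x have processed pseudogenes, so reads shared with such copies leave their values uncertain.

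**Figure D1:**
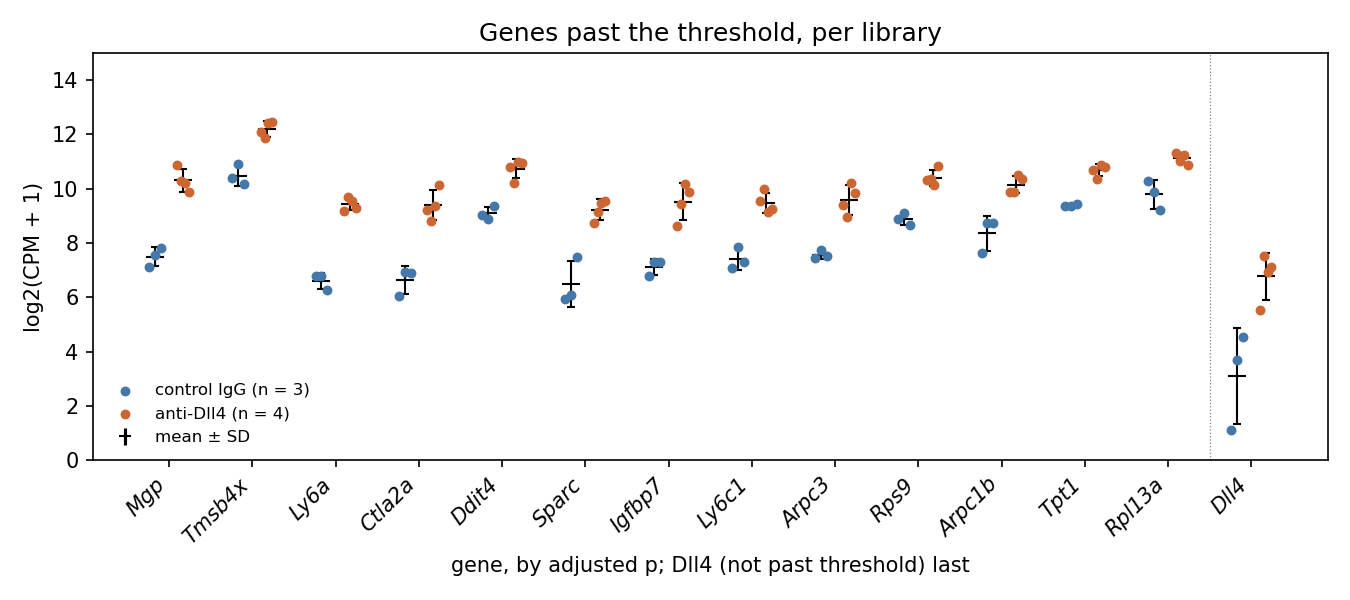
Values of the 13 genes past the threshold and of Dll4 in each library, on the log2(CPM + 1) scale, with the mean and SD of 3 control IgG and 4 anti-Dll4 libraries. For each of the 13 genes every anti-Dll4 point lies above every control point; Dll4 did not pass the threshold (adjusted p = 0.358).

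No gene was called lower in limma (0 genes), and 773 genes had an unadjusted p under 0.05 (401 higher and 372 lower), against 545 expected by chance. Of the 35 splits of the libraries into 3 and 4, 3 gave at least 773 such genes, the real one included, and the highest of the others gave 912. Voom on the whole reads called 40 genes, 16 higher and 24 lower. Groups did not overlap for 827 genes, 7.59% of those tested, where chance gives 5.71%. The count of 13 fell to 4 without control IgG 1, to 6 without anti-Dll4 1 or anti-Dll4 2 and to 3 without anti-Dll4 4, and rose to 20 without control IgG 3. It was 0 without the mean-variance trend and 1 (Mgp) with the rod marker mean as a covariate. A replicate block gave 3 genes on title numbers, 1 of them among the 13, and 4 on column numbers. Without the trend the changes are the same by construction and their median SE over the 13 genes went from 0.35 to 0.63. With the covariate the changes of the 13 ran from 1.10 to 2.97, against 1.29 to 2.83, and the median SE was 0.45. With a library left out in turn, Mgp, Tmsb4x and Ly6a passed in all 7 fits, Ctla2a in 5, Ddit4 and Sparc in 4 and Igfbp7 in 3. Arpc1b, Arpc3, Ly6c1 and Rps9 passed in 2, Rpl13a in 1 and Tpt1 in 0. With libraries scaled on endothelial markers the split was 1 higher (Edn2) and 270 lower, and that scaling moved the median log2 change of all genes from -0.14 to -1.39.

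Markers of endothelial cells in general rose. Of 19 tested markers, 16 had a positive change, with a median of 1.56 on the log2 scale, and the mean of the list went from 5.30 ± 0.80 (SD, n = 3) to 6.56 ± 0.25 (SD, n = 4) log2 units (camera adjusted p = 5.2e-07, adjusted p = 0.198 with an estimated correlation). As a share of all CPM, these markers made up 0.227% ± 0.0564 in control and 0.470% ± 0.0427 in anti-Dll4 libraries (exact permutation p = 0.0286, the smallest that 35 splits can give, two-sided). For the list means the exact permutation p was 0.0286 before and 0.176 after adjustment over lists. The mean change of 1.25 fell to 0.83 without control IgG 4 and kept its call. Ly6c1 passed over all genes, and 5 passed adjusted over the list alone: Ly6c1, Esam, Cldn5, Egfl7 and Cd34. Of these, Cd34, which is also in the tip cell list, had groups that overlap. It had 143, 277 and 1 reads in control and 573, 466, 793 and 352 in anti-Dll4 libraries. Esam, an endothelial adhesion molecule, had a log2 change of 1.74 ± 0.38 and Cldn5, the main tight junction claudin of endothelium, 1.56 ± 0.47. Kdr and Flt1, which encode VEGF receptors and are also in this list, had changes of -0.46 ± 0.47 and -0.38 ± 0.41, and Pecam1 0.34 ± 0.53.

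Further lists of vascular genes rose by the camera test. They share members with each other or with the general endothelial list (among them Esam, Cldn5, Cd34, Dll4 and Col4a1), so they are not separate results. Positive and negative changes numbered 11 and 10 for tight junction (median 0.11) and 11 and 8 for arterial lists (0.35). They numbered 14 and 5 for tip cell (0.58) and 12 and 5 for basement membrane lists (1.20). The unadjusted exact permutation p was 0.0286, 0.171, 0.114 and 0.114 in that order. The basement membrane list (17 tested, mean change 0.90, adjusted p = 7.2e-05, or adjusted p = 0.198 with an estimated correlation) had Sparc past the threshold over all genes and Sparc, Fn1 and Sparcl1 adjusted over the list alone; its mean turned to -0.35 under scaling on endothelial markers, 1.04 above the median gene. The list for tight junctions and barrier transporters (21 tested, mean change 0.39, adjusted p = 0.00993, or adjusted p = 0.198 with an estimated correlation) had 0 members past the threshold over all genes and 4 adjusted over the list alone, Esam, Slc7a5, Slc2a1 and Cldn5. Slc7a5, a carrier of large neutral amino acids at the blood-retina barrier, had a log2 change of 2.02 ± 0.45 and Slc2a1, the glucose transporter GLUT1, 1.52 ± 0.37. The arterial list (19 tested, mean change 0.83, adjusted p = 0.0252, or adjusted p = 0.267 with an estimated correlation) had 3 members adjusted over the list alone, Mgp, Edn1 and Dll4, and the tip cell list (19 tested, mean change 0.89, adjusted p = 0.00993, or adjusted p = 0.267 with an estimated correlation) Dll4, Cd34 and Adm. Edn1, the precursor of the vasoconstrictor endothelin 1, had 31, 0 and 1 reads in the control libraries and 102 to 280 in the anti-Dll4 libraries.

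Lists for shear stress response (mean change 1.18, adjusted p = 0.00993, or adjusted p = 0.198 with an estimated correlation) and for TGF-beta and BMP signalling (mean change 0.82, adjusted p = 0.00993, or adjusted p = 0.267 with an estimated correlation) had 0 members past the threshold over all genes and 0 adjusted over the list alone. The list of signals from endothelium to mural cells (mean change 0.90, adjusted p = 0.0252, or adjusted p = 0.217 with an estimated correlation) had Edn1 and Ece1, the enzyme that makes endothelin 1, adjusted over the list alone, and the list of leukocyte adhesion and cytokine genes (mean change 1.13, adjusted p = 0.0194, or adjusted p = 0.224 with an estimated correlation) had Nfkbia. Under scaling on endothelial markers, which shifts all genes of a library alike, the mean changes of these vascular lists were below 0, that is, smaller than that of the endothelial markers. The unadjusted exact permutation p was 0.0286 for TGF-beta and BMP, 0.0571 for shear stress, 0.0857 for mural signal and 0.114 for leukocyte adhesion lists. Leaving out a library ended 7 of the camera calls of vascular lists. The arterial call ended without control IgG 1 or anti-Dll4 1, 2 or 3 (adjusted p = 0.0707 to 0.133). The tip cell call ended without control IgG 1 or anti-Dll4 3 (0.0995 and 0.127, the mean change being 0.55 without anti-Dll4 3) and the tight junction call without control IgG 4 (0.0615). The TGF-beta and BMP call ended without control IgG 1 or anti-Dll4 4 (0.113 and 0.0622). The call for mural signals ended without control IgG 4, anti-Dll4 1 or anti-Dll4 2 (0.105, 0.104 and 0.0994, the mean change being 0.57 without control IgG 4). The shear stress call ended without anti-Dll4 1 (0.0767) and the leukocyte adhesion call without control IgG 1 or anti-Dll4 4 (0.0685 and 0.0699). The rod marker mean as a covariate ended 6 of these calls. With it, the tip cell mean went from 0.89 to 0.06 (adjusted p = 0.982), and basement membrane from 0.90 to 0.21 (0.247). The leukocyte adhesion mean went from 1.13 to 0.52 (0.247), tight junction from 0.39 to 0.27 (0.247), arterial from 0.83 to 0.90 (0.137) and shear stress from 1.18 to 1.09 (0.0531).

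Transcripts of cytosolic ribosomal proteins rose as a group. Of 33 tested, 29 had a positive change, with a median of 1.21, and the list mean went from 6.67 ± 0.14 (SD, n = 3) to 7.81 ± 0.34 (SD, n = 4) log2 units (camera adjusted p = 1.0e-15, adjusted p = 0.148 with an estimated correlation), although under scaling on endothelial markers the mean change turned to -0.12, 1.27 above the median gene. Their share of all CPM went from 0.551% ± 0.0487 to 1.08% ± 0.221 (exact permutation p = 0.0286, two-sided). For the list means the exact permutation p was 0.0286 before and 0.176 after adjustment over lists. Rps9 passed over all genes and 8 members adjusted over the list alone.

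Interferon response genes rose as well, with positive changes for 22 of 23 and a median of 1.74. The list mean went from 4.13 ± 0.49 (SD, n = 3) to 5.75 ± 0.55 (SD, n = 4) log2 units (camera adjusted p = 2.6e-11, adjusted p = 0.148 with an estimated correlation). The exact permutation p of these means was 0.0571 before and 0.235 after adjustment over lists (two-sided). No member passed over all genes and 7 passed adjusted over the list alone. H2-K1 and H2-D1, heavy chains of class I histocompatibility molecules that are similar enough to share reads, had log2 changes of 1.57 ± 0.33 (adjusted p = 0.0656) and 1.97 ± 0.42 (adjusted p = 0.0693). Relative to the general endothelial markers the mean change was 0.37 (95% interval -0.62 to 1.35, exact permutation p = 0.4, two-sided), which is within the spread between libraries.

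**Figure D2:**
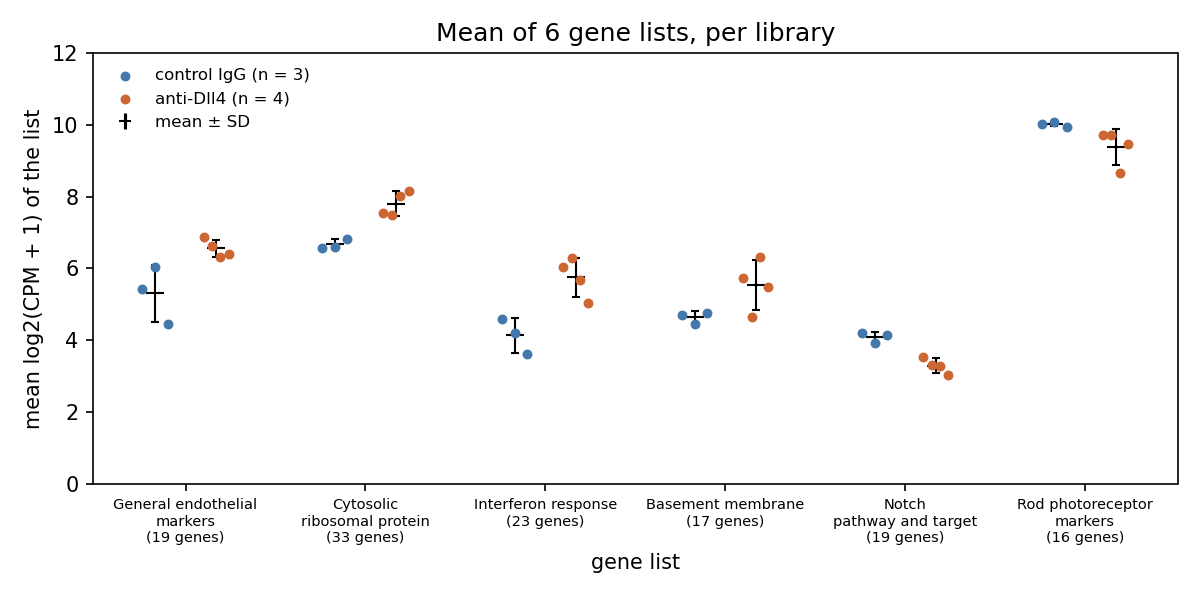
Mean log2(CPM + 1) of 6 gene lists in each library, with the mean and SD of 3 control IgG and 4 anti-Dll4 libraries. The ribosomal protein means lie at 6.67 ± 0.14 and 7.81 ± 0.34 as deposited (scaling on endothelial markers turns this change to -0.12), and the anti-Dll4 libraries lie above the controls for the general endothelial and interferon lists and below them for the Notch and rod lists.

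Rod photoreceptor markers fell. Of 16 markers, 14 had a negative change, with a median of -0.65, and the list mean went from 10.01 ± 0.06 (SD, n = 3) to 9.39 ± 0.50 (SD, n = 4) log2 units (camera adjusted p = 6.7e-07, adjusted p = 0.224 with an estimated correlation). As a share of all CPM, rod markers made up 2.83% ± 0.0718 in control and 1.8% ± 0.442 in anti-Dll4 libraries (exact permutation p = 0.0571, two-sided). Anti-Dll4 3 stood apart at 8.66 log2 units against 9.45 to 9.72 in the other anti-Dll4 libraries, and without it the mean change went from -0.63 to -0.38 and kept its call. No rod marker passed over all genes and 9 passed adjusted over the list alone, 8 of them lower. Nr2e3, a rod transcription factor, had a log2 change of -1.15 ± 0.29 (adjusted p = 0.178). This lower share of rod RNA stood beside each of the groups that rose, in the same 4 libraries.

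The means of cone (-0.79), bipolar (-0.85), amacrine (-0.52) and ganglion cell (-0.90) marker lists were below 0 without passing the test (adjusted p = 0.183, 0.124, 0.346 and 0.226). Astrocyte (-0.48, adjusted p = 0.392), pericyte (-0.35, adjusted p = 0.548) and red blood cell markers (-0.55, adjusted p = 0.365) did not pass either, nor did Müller glia (0.22, adjusted p = 0.309), microglia (0.41, adjusted p = 0.475), smooth muscle (0.54, adjusted p = 0.346) and lens markers (1.23, adjusted p = 0.226). Vim, an intermediate filament gene in the Müller glia list that endothelial cells also express, had a log2 change of 2.44 ± 0.51 (adjusted p = 0.0656). Pigment epithelium and lymphocyte lists had 3 tested members each, with mean changes of -1.21 and 0.70.

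The Notch list had a median change of -0.92, with 13 of 19 members negative, and did not pass (camera adjusted p = 0.197, fry adjusted p = 0.0667). Its mean was lower in every anti-Dll4 library than in every control library, at 4.09 ± 0.15 (SD, n = 3) and 3.29 ± 0.21 (SD, n = 4) log2 units (exact permutation p = 0.0286 before and 0.176 after adjustment over lists, two-sided). None of its members passed. In the same libraries the mean of the bipolar, cone, ganglion and amacrine cell lists changed by -0.76 (exact permutation p = 0.0571). The ganglion cell list alone changed by -0.90, again with groups that did not overlap (exact permutation p = 0.0286). Transcripts of Dll4 itself were at 11.7 ± 10.5 CPM in control and 122 ± 57.5 CPM in anti-Dll4 libraries, a log2 change of 3.67 ± 1.10 (adjusted p = 0.358), from 2, 16 and 34 reads against 68, 300, 211 and 246. The Notch target Hey1 had a change of -3.11 ± 1.79, Hes1 of 0.74 ± 1.35 and Nrarp of -0.87 ± 1.70. Hes1 had 192, 1 and 172 reads in control and 84, 15, 229 and 113 in anti-Dll4 libraries. Its mean CPM was lower in anti-Dll4 libraries (64.7, against 75.4 in control), so its direction is uncertain. The receptors Notch1 and Notch4 had changes of 0.63 ± 0.98 and 1.11 ± 1.21, and the ligand Jag1 of -0.92 ± 0.48. Hey2, another target, was below the filter, with 53, 0 and 26 reads in control and 0, 0, 0 and 1 in anti-Dll4 libraries. Efnb2 and Gja4, arterial genes, were also below the filter at 7.82 ± 13 and 0 CPM in control and 1.12 ± 1.51 and 2.77 ± 5.10 CPM in anti-Dll4 libraries, and Gja5 was not analysed here.

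**Figure D3:**
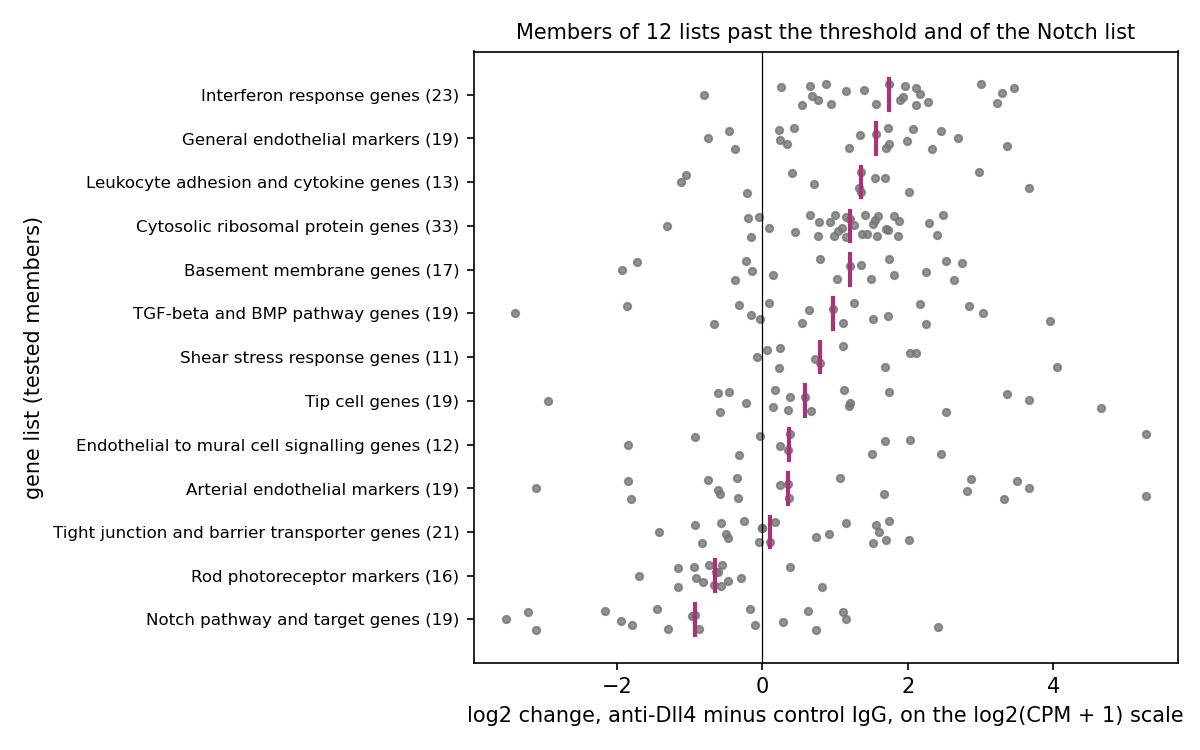
Log2 change (anti-Dll4 minus control IgG, log2(CPM + 1) scale, values as deposited) of each tested member of the 12 lists past the threshold and of the Notch list, which did not pass; grey points are genes and the thick bar is the list median. Medians run from 1.74 for interferon response genes to -0.65 for rod markers and -0.92 for the Notch list; scaling on endothelial markers shifts all genes alike and puts the mean changes of the other lists with positive medians below 0, except the interferon list (0.37, exact permutation p = 0.4) and the endothelial list, which it sets to 0.

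The other endothelial and pathway lists did not pass. Venous markers had a mean change of 0.99 (adjusted p = 0.086), capillary markers 0.17 (0.817), caveola and vesicle trafficking genes 0.31 (0.235), Wnt and norrin genes 0.47 (0.178), and oxidative phosphorylation genes 0.43 (0.0611). VEGF pathway genes had a mean of -0.02 and a median of 0.07 (0.999), proliferation genes -0.12 (0.8), cell cycle inhibitors 0.27 (0.392), and Myc targets and ribosome biogenesis genes -0.49 (0.226). Immediate early genes had a mean of 0.32 (0.183), glycolysis and hypoxia genes 0.27 (0.153), stress and unfolded protein response genes -0.22 (0.901) and apoptosis genes 0.49 (0.114). In the capillary list, Tfrc, the transferrin receptor, had a log2 change of -1.88 ± 0.55 (adjusted p = 0.358), while Slc7a5 in the same list was at 2.02 ± 0.45.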

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

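All tests in this part were chosen before the data were examined. In the anti-Dll4 group, 83 named genes and 37 lists were checked for a library far from the other 3, meaning a gap, as a part of the group's range, above Dixon's 95% critical value for 4 libraries. The check picked out 12 genes and 1 list, where chance gives about 6. For 7 of the genes the other 3 libraries had at most 1 read each, where that chance rate does not hold, so no excess is read from the count. Of the 12 genes, 5 had a low library: Edn1 in anti-Dll4 2 (gap 0.914 of the range; 5.99 log2 units against 7.20 to 7.31), Adgra2 in anti-Dll4 4 (0.922; 8.85 against 9.57 to 9.63), Vegfa in anti-Dll4 4 (0.958; 2.85 against 6.35 to 6.50), Bbc3 in anti-Dll4 2 (0.895; 5.64 against 7.59 to 7.82) and Mylk in anti-Dll4 3 (0.859; 7.09 against 8.52 to 8.75).

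The genes with a high library were Hey1 in anti-Dll4 1 (gap 0.872; 5.36 against 0 to 0.69), Rdh5 in anti-Dll4 3 (0.897; 6.30 against 0 to 0.65) and Snap23 in anti-Dll4 4 (0.831; 4.07 against 0 to 0.69). Dll1 in anti-Dll4 1 (2.81), S100b (1.09), Sncg (2.60) and Cabp2 (1.43) in anti-Dll4 4 were each at 0 in the other 3 libraries, so the gap was 1 of the range. The immediate early gene list was high in anti-Dll4 2 (0.898; 6.21 against 5.64 to 5.70).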

How the results depend on the processing

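Alternatives added after the data were seen were voom on the whole reads, a pseudocount of 0.25, scaling on endothelial markers and the block on column numbers. Of 13 genes changed, all higher, the count was 0 without the mean-variance trend, 29 with robust variances (28 higher, 1 lower), 23 with library weights, 25 at an adjusted p under 0.1 (24 higher, 1 lower), 1 with the rod marker covariate (Mgp; changes of the 13 at 1.10 to 2.97, against 1.29 to 2.83), 40 with voom (24 lower; 9 shared with the 13) and 271 under endothelial scaling (1 higher, 270 lower, 0 shared). Leaving out each library gave 3 to 20 genes, all higher, and 0 lower. Mgp, Tmsb4x and Ly6a kept their call in all 7 fits, Ctla2a in 5, Ddit4 and Sparc in 4, Igfbp7 in 3, Arpc1b, Arpc3, Ly6c1 and Rps9 in 2, Rpl13a in 1 and Tpt1 in 0. Apart from the replicate blocks below, the other settings stayed within 1.5 times. Re-logging at a pseudocount of 1 moves nothing, as the table is on that scale. The cause of these changes was not tested.

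With the title number as a replicate block, 3 genes passed: Tmsb4x higher (1 gene), and Rims2 and Sptan1 lower (2 genes). A block on column numbers gave 4 genes, all higher and among the 13. The same-numbered libraries' deviations correlated by 0.052, 0.046 and 0.067 (numbers 1, 3 and 4), against -0.037 to 0.015 for libraries with unlike numbers. These values are small, but each lies above those of all unlike pairs, so pairing cannot be excluded. The main fit held no block because no label pairs the libraries. On the blocks, 8 lists passed with title numbers (7 of the 12) and 11 with column numbers (10 of the 12). Each control correlated best with its own number, a hint from the data only.

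Of 37 lists, 12 passed, 0 with an estimated correlation, 0 with fry, 6 with the rod marker covariate (5 of the 12) and 9 to 15 with each library left out. By the exact permutation test, whose p cannot go below 0.0286, 0 lists passed after adjustment over lists. With an estimated correlation and with fry the mean changes stay as they are by construction and no call remained: general endothelial 1.25 (adjusted p = 0.198 and 0.0832), basement membrane 0.90 (0.198 and 0.161), ribosomal 1.13 (0.148 and 0.0667), interferon 1.62 (0.148 and 0.0667) and rod -0.63 (0.224 and 0.169). The rod covariate ended the calls of basement membrane (0.21, adjusted p = 0.247), tip cell (0.06), leukocyte adhesion (0.52), tight junction (0.27), arterial (0.90) and shear stress lists (1.09). It also ended that of the rod list, which it sets to 0 by construction. The call gained with the covariate was of red blood cell markers, lower by camera (mean change -1.60, adjusted p = 0.0237). That list was called under endothelial scaling too (-1.81, adjusted p = 0.00811). Its members vary together (estimated correlation 0.98), far above the preset 0.01. The 5 lists given above with fry kept their calls in all 7 fits with a library left out, with mean changes of 0.83 to 1.62 (general endothelial, lowest without control IgG 4), 0.64 to 1.20 (basement membrane), 1.02 to 1.24 (ribosomal), 1.36 to 1.86 (interferon) and -0.74 to -0.38 (rod, smallest without anti-Dll4 3). Under endothelial scaling, which lowers all genes, mean changes turned negative for ribosomal (-0.12), basement membrane (-0.35), arterial (-0.42), venous (-0.26), tip cell (-0.36), tight junction (-0.86), TGF-beta and BMP (-0.43), mural signal (-0.35), shear stress (-0.074) and leukocyte adhesion lists (-0.13). These signs follow from the shift. Camera, which compares a list with the other genes, called 13 lists there, 10 of the 12, among them ribosomal (adjusted p = 0.000462), basement membrane (0.0068) and arterial (0.0191). Planned count-model tests on the reads were not run. At the read totals of these libraries (1356192 to 1771086 reads) and a spread averaged over the groups, 4.48% of genes changed 2-fold were recovered in simulation. Most such genes would be missed. The simulation did not vary the depth.

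Of 1811 alternative values of 83 named genes, 1673 kept direction and side of the threshold, 86 lost a call, 32 gained one and 20 changed sign, none of them called. Most named genes had no call to lose. All 11 that were past the threshold lost their call in some setting. Of 883 values of lists, 45 changed sign. Of these, 10 belonged to lists called by camera as deposited or in that setting, which are the 10 given above under endothelial scaling. Among them the venous list was called only under that scaling (adjusted p = 0.0191). The tight junction and mural signal lists were called only as deposited (adjusted p = 0.744 and 0.187 under that scaling). There, uncalled lists also turned negative: capillary (-1.08), caveola and vesicle trafficking (-0.94), Wnt and norrin (-0.78), cell cycle inhibitor (-0.98), oxidative phosphorylation (-0.83), glycolysis and hypoxia (-0.98), immediate early (-0.93), apoptosis (-0.76), Muller glia (-1.03), microglia and macrophage (-0.84), smooth muscle (-0.72) and lens lists (-0.025). So did Cavin1 (-0.28), Cdkn1b (-0.036), Hes1 (-0.51), Hspa5 (-0.58), Ier3 (-0.50), Notch1 (-0.62), Notch4 (-0.15) and Tubb5 (-0.75). The rod marker covariate turned the stress and unfolded protein response list to 0.34, microglia and macrophage markers to -0.12, Crygb to -0.68, Hes1 to -0.90, Mylk to 0.23 and Tubb5 to -0.41.

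With the title number block, the sign changed for capillary (-0.031), VEGF pathway (0.040), proliferation (0.47) and red blood cell lists (0.012), Cd79b (0.29), Nrarp (0.54) and Rdh5 (1.18). The VEGF pathway list, near 0 as deposited, was at 0.086 with no filter, 0.22 with a stricter filter, 0.085 with quantile normalization, 0.0072 with the median shift, 0.042 with log2(CPM + 5), 0.0084 with library weights and 0.12 with the column number block. The proliferation list was at 0.16 with quantile normalization and 0.097 with the column number block. With each library left out, changes ran from -1.74 to 0.045 for Des, -1.95 to 0.32 for Hba-a1 and Hba-a2, -1.27 to 1.75 for Hes1 and -2.26 to 0.40 for Nrarp. For lists they ran from -0.075 to 0.39 (capillary), -0.40 to 0.097 (proliferation), -1.46 to 0.20 (red blood cell), -0.38 to 0.035 (stress and unfolded protein response) and -0.27 to 0.26 (VEGF pathway).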

Other observations

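Tests of the endothelial and rod share, and that of transcript length for endothelial markers, were chosen after the results were seen; the count of splits and the length tests for the other lists were not. The test of falling endothelial markers was set when their changes were known, and it replaced a test of their spread that had counted against a larger endothelial share. Several genes outside the rule, chosen after their values were seen, were higher in every anti-Dll4 library without passing the threshold. Edn2, the precursor of the vasoconstrictor endothelin 2, had 0, 0 and 3 reads in control and 101, 116, 715 and 551 in anti-Dll4 libraries (adjusted p = 0.0538). Txnip, an inhibitor of thioredoxin, had a log2 change of 2.98 ± 0.61 (adjusted p = 0.0538) and the metallothionein gene Mt2 3.52 ± 0.82 (adjusted p = 0.130). The related Mt1 changed by 0.82 ± 1.71 (adjusted p = 0.945), with groups that overlap. Adm, which encodes the vasodilator adrenomedullin, had 0, 14 and 0 reads against 95, 68, 149 and 74 (adjusted p = 0.482).

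RNA of other cells was measured in all libraries. Hba-a1, a haemoglobin chain of red blood cells, ran from 565.9 to 7969 CPM in control and from 255.8 to 14872 CPM in anti-Dll4 libraries. The gene with the highest mean was Akap5 at 13255 CPM, and the rod genes Nr2e3 and Rom1 had means of 3900.1 and 3700.4 CPM. Between 50 and 259 genes per library had at most 1 read although each other library of the group had at least 20 CPM. Anti-Dll4 3 lay far from the rest on the first principal component (195 against -58.4 to 17.1).

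The 13 genes were set against other groupings of the libraries. Of the 35 splits of 7 libraries into 3 and 4, 1 (the real one) gave as many genes, and the highest of the others gave 7. That is a share of 1 in 35, the smallest these libraries can give, so chance can be excluded at no stricter level. At an unadjusted p under 0.05 the real split gave 773 genes and other splits gave up to 912 and 889, so that count does not set the real split apart. The 13 fell to 3 without anti-Dll4 4 and to 0 without the mean-variance trend.

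General endothelial markers were higher. Length bias had little room to act, as the median length was 3249 bases against 3122 over all genes. The list's median lay at percentile 100 of 10000 random lists matched on length and expression. Such percentiles, here and for the lists below, measure the spread between genes and not between libraries, and they take genes as independent. A smaller rod share as the whole cause would raise other non-rod RNA alike. Relative to bipolar, cone, ganglion and amacrine cell markers, the endothelial list rose by 2.02 (95% interval 0.67 to 3.36, exact permutation p = 0.0286, the smallest possible). Those neuron lists themselves changed by -0.76 (exact permutation p = 0.0571). The comparison therefore counts only against a fall confined to rods, and less RNA of retinal neurons in general stays open. It replaced, after results were seen, the rod covariate test that is used for the lists below. With that covariate the endothelial mean change was 1.56 (95% interval -0.09 to 3.22), which includes 0 and does not decide. A larger endothelial share as the whole cause cannot be told apart from a response to the antibody. A larger share should lower no marker, and 0 of the 19 had an interval below 0, but that test was set with the changes known and decides nothing. The upper limits of Kdr and Flt1, abundant markers noticed after the fact, were 0.52 and 0.48, below the common change of 1.12 that a single factor needs. That counts against a single factor for these 2 genes, unless RNA of other cells, which was not measured for them, held them level. The replaced test found that the changes spread widely (Cochran's Q 47.9, highest other split 41.0). The other splits hold no common rise, and low counts or RNA of other cells may make markers rise unequally, so that spread does not decide.

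For ribosomal protein genes, short transcripts (median 964 bases against 3122 over all genes) were a candidate explanation, as changes fell with length across genes (Spearman -0.10), and matched lists had a median of 0.32; the list, at 1.21, lay at percentile 99.99. With the rod covariate the mean change was 0.85 (95% interval 0.16 to 1.54, against 1.13 without). The rod mean varied little between control libraries (SD 0.06, n = 3) and more between anti-Dll4 libraries (SD 0.50, n = 4). The covariate's slope therefore rests mostly on the anti-Dll4 libraries. The interval counts at most against a fall confined to rods, and less RNA of retinal neurons in general stays open. Relative to the endothelial marker mean, the change was -0.12 (95% interval -1.55 to 1.31, exact permutation p = 0.857), so a larger endothelial share cannot be told apart from a change in these cells.

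For interferon response genes, length-matched lists had a median of -0.03 and the list, at 1.74, lay at percentile 100. With the rod covariate the mean change was 1.88 (95% interval 0.26 to 3.51, against 1.62 without). As for the ribosomal list, the covariate's slope rests mostly on the anti-Dll4 libraries. The interval counts at most against a fall confined to rods, and less RNA of retinal neurons in general stays open. Relative to the endothelial marker mean, the list was higher by 0.37 (95% interval -0.62 to 1.35, exact permutation p = 0.4), so the endothelial share and a response to the antibody cannot be told apart with 7 libraries. That endothelial interferon and class I genes may respond to the antibody stays a hypothesis.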
